A study of Mus musculus with 12 samples.

How the data were processed

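Polyadenylated RNA was sequenced from 12 libraries of V6.5 mouse embryonic stem cells, a C57Bl/6-129 hybrid line grown on gelatin with LIF. The endogenous Cdk13 gene was knocked out and the cells carried an epitope-tagged Cdk13 transgene that doxycycline switches on, per the labels. Libraries came from 2 independently derived clones (11-8 and 14-1), with 2 libraries per clone kept in doxycycline, 2 per clone taken after 48 h without it and 2 per clone after 72 h, so that each condition had 4 libraries. The labels describe the 2 libraries of a clone and condition as biological duplicates. Strand-specific mRNA libraries were made from RNA whose integrity number (RIN) was at least 8.9, per the labels' protocols.

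The data were 1 table of the authors' own comparison, in which each row is an exon part, a stretch of a gene counted as a unit. Exon parts were quantified with DEXSeq, per the file headers. For each part the authors gave an FDR-adjusted p-value and a log2 fold change, cells without Cdk13 over cells with it, at 48 h and at 72 h of depletion, per the file headers. DEXSeq models the use of a part relative to the other parts of its gene, so the fold changes are read here as changes in relative use and not in the amount of the gene's RNA. STAR 2.4.1d and the mouse build mm9 are named in the submitters' processing notes. The counting step, the annotation behind the exon parts, the DEXSeq version, any shrinkage of the fold changes and the use of clone in the model are not given in the sources used here. The authors' classes of parts, per the file headers, include first exons, terminal (most 3′) exons, cassette exons, detained introns, intronic polyadenylation parts and unclassified parts, which are mostly internal constitutive exons. A detained intron is an intron kept in otherwise spliced, polyadenylated transcripts. Another 3 class labels, on 123 parts, have no definition in the header.

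The table held 138745 parts under 15139 gene names. A spreadsheet had turned 22 gene names into dates, and these were restored from the part identifiers. Values per library are not used here, so the sequencing depth per library, a spread between replicates, a comparison of the clones, gene-level expression, fits with a replicate left out, other splits of the samples and a repeat of the test with another tool could not be computed. An adjusted p was given for 42340 parts (30.5%) of 7026 genes at 48 h and for 105545 parts (76.1%) of 11600 genes at 72 h. Every part with an adjusted p at 48 h had one at 72 h. A part was called changed at the authors' adjusted p below 0.05, which matched the authors' own significance column in every row. Parts with no adjusted p were counted as not tested and never as unchanged. Coordinates are those of the table, on mm9, counted from 1 with both ends included. Under that reading the width of 76.6% of 88544 internal unclassified parts equalled the width of an annotated exon of the gene (GENCODE M21), against 11.2% or 11.3% when the widths were shifted by 1 base. No coordinates were taken from that annotation, which is on another build.

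Parts were ordered from the 5′ to the 3′ end of each gene by strand, and the 5′ and 3′ sides of a gene were the parts before and after the middle of that order, in genes with at least 3 parts in the table. Direction against side, direction against class, and gene lists against other tested genes were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the classes with called parts within a time and over the 28 list tests (14 lists at 2 times). These tests take parts or genes as units. Parts of a gene depend on each other, because a lower share of one part raises the others, and units are not replicate cultures, so these p-values describe the pattern within 1 table. A list test was repeated with genes stratified into 5 groups by their number of tested parts (Mantel-Haenszel), for lists with at least 5 tested genes. That minimum of 5 was set after the test had failed on smaller lists. Counts adjusted over the list alone used p-values worked back from the adjusted p by rank, which is approximate, because tied adjusted p-values give an upper bound. List genes were matched to the table by symbol (374 list entries) or by a single older name in a table of RefSeq genes of GRCm38.p6 (12 entries), and older names that are another gene's own symbol were not used. The lists, the designs and the rule for named genes were fixed before the data were examined. The rule took, at each time and among called parts, 1 part per gene (lowest adjusted p), the 10 genes with the largest rise and the 10 with the largest fall, up to 4 genes per list with the lowest adjusted p at 72 h, and Cdk13, Cdk12 and Ccnk whatever their values. A minimum on the mean count was part of the rule but could not be applied.

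Both times were compared with the same libraries in doxycycline. The overlap of calls was therefore set beside the overlap of independent lists and beside a simulation of unchanged groups of 4 libraries against shared controls (400000 simulated parts). With 4 control libraries but no values per library, the controls could not be split. Gradients along genes were the mean log2 fold change of the most 5′ of 3 equal groups of a gene's exonic parts minus that of the most 3′ group, in genes with at least 6 such parts, leaving out parts wider than 10000 bp, detained introns and intronic polyadenylation parts. These limits were set after the table was seen. Correlations across genes used 100000 permutations, and intervals came from 2000 bootstrap draws over genes (1000 for each of 5 position groups along genes). Computations ran in Python 3.11.15 with scipy 1.17.1, statsmodels 0.14.6, numpy 2.4.6 and pandas 2.3.3.

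The statistics were tested on simulated data with the table's own genes and parts. With parts of 200 genes shifted, 96.8% of the shifted parts were recovered for the 48 h layout (42340 parts) and 96.6% for the 72 h layout (105545 parts), and 5.03% and 5.05% of calls were false. Of 200 random lists of genes, 2.50% at 48 h and 3.50% at 72 h had p below 0.05, and after 100 shuffles of direction over the called parts the position test fell below 0.05 in 6.00% and 4.00%. The shuffles ran across genes and did not keep the dependence between parts of a gene, so they do not test its effect on the p-values. The p-values worked back from adjusted values lay within 1% of the simulated ones for 68.2% of parts at 48 h and 90.2% at 72 h and were never below them. Gradients planted on exonic length alone gave a partial correlation of 0.25 with exonic length and -0.01 with genomic span over 2763 genes at 48 h, and 0.31 and -0.02 over 6682 genes at 72 h.

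Alternatives were adjusted p thresholds of 0.01 and 0.1, a minimum absolute log2 fold change of 1, 1 part per gene, the end groups of genes divided in 3, genes with at least 6 parts, stratified list tests and lists counted by genes with at least 2 changed parts. Chosen after seeing the data were the restriction to parts tested at both times, the position test without detained introns and intronic polyadenylation parts or with unclassified parts only, lists counted by detained introns only, and the adjustment over each list alone.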

Results

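Polyadenylated RNA was profiled in mouse embryonic stem cells that lacked their own Cdk13 and lived on a doxycycline-dependent Cdk13 transgene. CDK13 is a cyclin K-dependent kinase that phosphorylates the C-terminal domain of RNA polymerase II. The series, titled after nuclear RNA surveillance, asked how the use of exon parts changed when Cdk13 was withdrawn for 48 h or for 72 h. There were 12 libraries from 2 clones, 4 per condition. No library came from cells without the transgene taken off doxycycline. Effects of Cdk13 loss and of removing the drug therefore cannot be told apart. RNA integrity numbers were 9.10 ± 0.14 (SD, n = 4) with doxycycline, 9.05 ± 0.17 (SD, n = 4) at 48 h and 9.05 ± 0.17 (SD, n = 4) at 72 h. Depth per library is unknown here, and the fold changes and adjusted p-values below are those of the authors, with no spread between replicates of their own.

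Cdk13 itself gave little information on its own loss, because the values are relative to the rest of each gene. None of its 14 parts had an adjusted p at 48 h. At 72 h, 1 intronic polyadenylation part (E022, chromosome 13, 17835992 to 17842090, minus strand) was higher, at a log2 fold change of 0.95 and adjusted p of 0.010 in the authors' deposited table, and the 8 other parts with values were not called. Reads of the transgene and of the knocked-out Cdk13 gene were not told apart in these values. The rise of E022 therefore does not show a change in polyadenylation. Cdk12, the closest relative of Cdk13, had 1 called part at 48 h, the 5′-most part E001 (chromosome 11, 98071678 to 98072550), at 0.11 with adjusted p of 0.028 in the authors' deposited table. At 72 h that part stood at 0.10 with adjusted p of 0.10 in the authors' deposited table, and no part of Cdk12 was called. Ccnk, which encodes cyclin K, gained its detained intron E013 (chromosome 12, 109434790 to 109437517) at 72 h, by 0.38 with adjusted p of 0.0014 in the authors' deposited table.

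After 48 h without doxycycline, changes in exon use were small and split by the kind of part: first exons rose and terminal exons fell. Psmb10, an immunoproteasome subunit, had the largest rise when each gene was represented by its called part of lowest adjusted p, 0.45 for part E009 (chromosome 8, 108461579 to 108461666) with adjusted p of 8.6e-34 in the authors' deposited table. Among the other 9 largest rises, first exons rose in Aldoa (0.34), the glycolytic aldolase, in Triml1 (0.32), in 2810407C02Rik (0.24) and in Acin1 (0.23), which encodes a splicing-associated protein, in the authors' deposited table. Detained introns rose by 0.34 in H2afy, the gene of the histone variant macroH2A1, by 0.26 in Lck and by 0.23 in Slc9a8, an alternative first exon rose by 0.35 in Macf1, and an unclassified part of BC032203 rose by 0.35, per the authors' deposited table. The largest falls under the same choice of part were intronic polyadenylation parts of the small nucleolar RNA host transcripts 1500012F01Rik (-0.57) and 2410006H16Rik (-0.40) and an internal part of Coil (-0.37), the gene of the Cajal body protein coilin, in the authors' deposited table. The other 7 were terminal exons, of Ssh1 (-0.34), Hsd3b7 (-0.33), Ptpn3 (-0.31), 9630033F20Rik (-0.29), Gse1 (-0.29), Traf4 (-0.28) and the receptor gene Notch1 (-0.27), in the authors' deposited table. In all, 686 parts of 500 genes (7.12% of tested genes) were called, of which 408 were higher, 268 lower and 10 had no fold change, with a median absolute log2 fold change of 0.08. No call reached an absolute log2 fold change of 1, and at an adjusted p below 0.01 the count was 303.

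After 72 h, more genes had called parts. With each gene again represented by its called part of lowest adjusted p, the largest rises were in internal parts of Kctd19 (1.68), Rfc5 (1.502), Plekha2 (1.42) and Etv2 (1.32), a transcription factor of blood and endothelial progenitors, in the authors' deposited table. The Rfc5 part (E023, chromosome 5, 117837446 to 117837702), in a gene for a subunit of the replication clamp loader, had an adjusted p of 6.3e-20 in the authors' deposited table. First exons rose in Grina (1.37), in the autophagy gene Map1lc3b (1.34) and in Pga5 (1.30), the 5′-most part rose in Pgf (1.23), and intronic polyadenylation parts rose in Abcc4 (1.35), a drug efflux transporter gene, and in Pdzd8 (1.32), whose only part in the authors' deposited table this was. The largest falls under that choice were in the first exon of Gpr56 (-1.41), in unclassified parts of BC002230 (-1.26), Tspan32 (-1.23), Il4i1 (-1.07), Ubash3a (-0.999), Tekt5 (-0.96) and the Polycomb-associated gene Asxl1 (-0.98), in the terminal exon of Dpep3 (-0.95), and in intronic polyadenylation parts of Hmgxb3 (-0.999) and the Mediator subunit gene Med27 (-0.94), in the authors' deposited table. None of these 20 parts had an adjusted p at 48 h. In all, 3804 parts of 2214 genes (19.1% of tested genes) were called, of which 2454 were higher, 1347 lower and 3 had no fold change. The median absolute log2 fold change was 0.16 (quartiles 0.08 and 0.36), and 32 calls reached an absolute log2 fold change of 1. The wider testing at 72 h entered this count: among the 42340 parts tested at both times, 686 were called at 48 h and 2442 at 72 h. Over the 474 parts called at both times with values at both, the median absolute log2 fold change was 0.081 at 48 h and 0.094 at 72 h.

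Detained introns, terminal exons and first exons each moved mostly in 1 direction at 72 h. Of 2609 tested detained introns, 385 were higher and 13 lower, and the higher ones lay in 331 of 1801 genes with a tested detained intron. The odds ratio of being higher, against other called parts, was 19.1 (95% interval 10.9 to 33.3, Fisher's exact test, adjusted p = 2.6e-59). Of 8054 terminal exons, 662 were lower and 48 higher (odds ratio 0.0206, interval 0.0152 to 0.0280, Fisher's exact test, adjusted p = 1.6e-287), and of 7169 first exons, 382 were higher and 45 lower (odds ratio 5.33, interval 3.89 to 7.32, Fisher's exact test, adjusted p = 1.9e-34). Over all parts with a value, called or not, the median log2 fold change was 0.18 for detained introns (quartiles 0.04 and 0.33), 0.05 for first exons and -0.04 for terminal exons. For first and terminal exons, at both times, an effect of class was not separated from the change with position along genes described below. Intronic polyadenylation parts went both ways, with 73 higher and 55 lower of 1899 tested, and their direction did not differ from that of other called parts (odds ratio 0.720, interval 0.504 to 1.03, Fisher's exact test, adjusted p = 0.15). Among parts tested at both times, however, 25 were lower and 8 higher at 72 h (Fisher's exact test, p = 1.4e-04). At 48 h, 145 first exons were higher and 4 lower, 116 terminal exons were lower and 7 higher, and 7 intronic polyadenylation parts were lower and 1 higher (Fisher's exact test, adjusted p = 6.2e-31, 1.1e-44 and 0.028). Detained introns were 4 higher and 1 lower of 189 tested at 48 h (Fisher's exact test, adjusted p = 0.80).

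**Figure D1:**
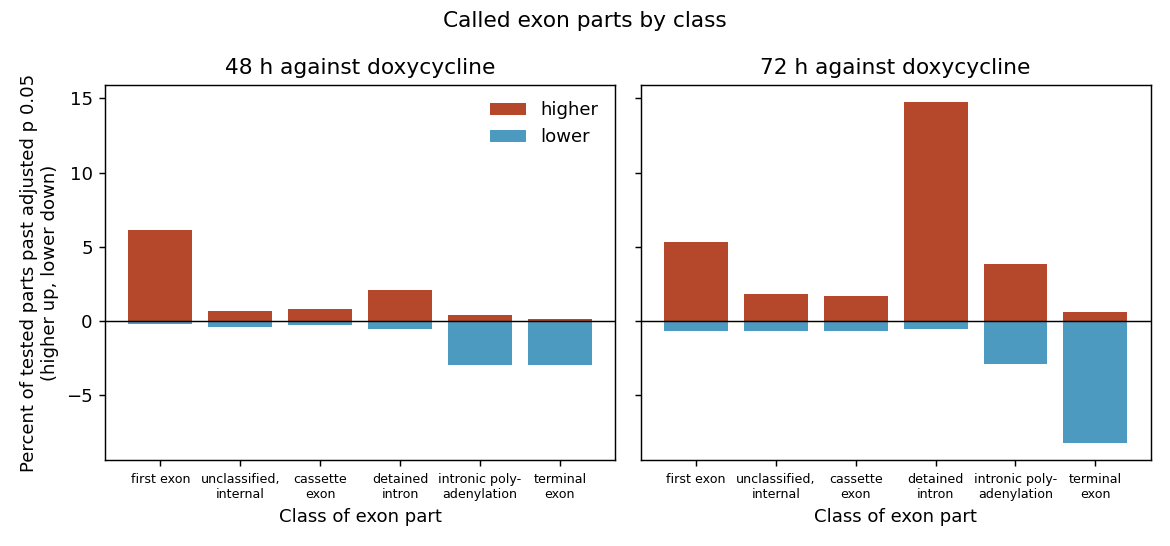
Percent of tested exon parts past the authors' adjusted p of 0.05, by class, at 48 h (left) and 72 h (right) without doxycycline against with it; bars above 0 are higher parts and bars below 0 lower parts. At 72 h, 385 of 2609 detained introns were higher and 662 of 8054 terminal exons lower.

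Along genes, use shifted from the 3′ end toward the 5′ end at both times. At 48 h, 337 of the higher parts lay on the 5′ side of their gene (84.5%) and 239 of the lower parts on the 3′ side (91.6%), an odds ratio of 59.0 (interval 35.3 to 98.7, Fisher's exact test, p = 1.8e-91). At 72 h, 1650 higher parts lay on the 5′ side (68.0%) and 1152 lower parts on the 3′ side (87.5%), an odds ratio of 14.8 (interval 12.3 to 17.8, Fisher's exact test, p = 1.0e-251). The median log2 fold change over all parts with a value went from 0.04 in the first of 10 equal groups of a gene's parts, counted from the 5′ end, to -0.02 in the last at 48 h, and from 0.06 to -0.04 at 72 h. In 354 genes at 72 h a higher part on the 5′ side stood with a lower part on the 3′ side, against 30 genes with the opposite arrangement, and at 48 h the numbers were 51 and 2. Fibronectin, Fn1 (chromosome 1, minus strand), had the most called parts of any gene at 72 h, 17 of 48 tested, and was singled out after its values were seen. Its first exon was higher by 0.12 and its terminal exon lower, at -0.13, in the authors' deposited table. With 1 part per gene the odds ratio was 100.5 at 48 h and 13.95 at 72 h, and with unclassified parts only 29.9 and 12.6. Among the parts with an absolute log2 fold change of at least 1 at 72 h, an association of position with direction was not shown (odds ratio 2.00, Fisher's exact test, p = 0.60). Calls of that size were few, 28 higher and 4 lower over all genes, so the test does not exclude an association.

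**Figure D2:**
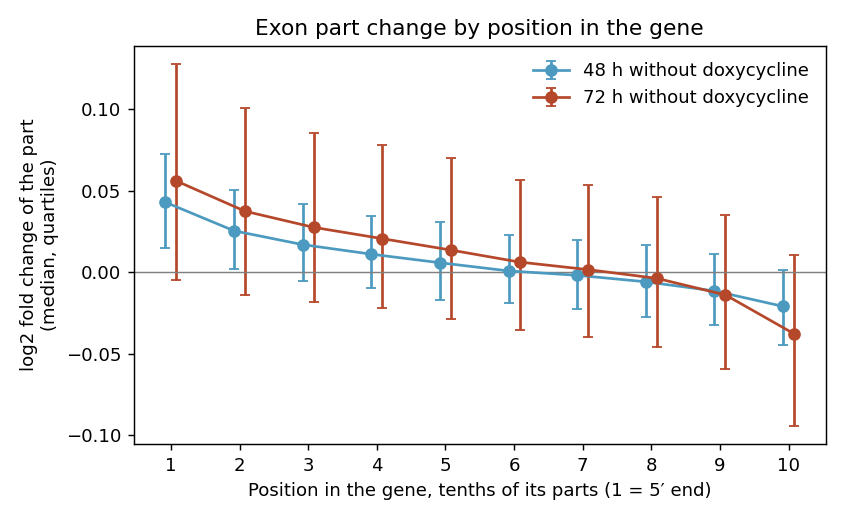
Median log2 fold change of exon parts (points) with quartiles (bars) by position in the gene, in 10 equal groups of the gene's parts from the 5′ end, at 48 h and 72 h without doxycycline. The medians fall at every step, from 0.04 to -0.02 at 48 h and from 0.06 to -0.04 at 72 h, while the quartiles overlap between neighbouring groups.

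**Figure D3:**
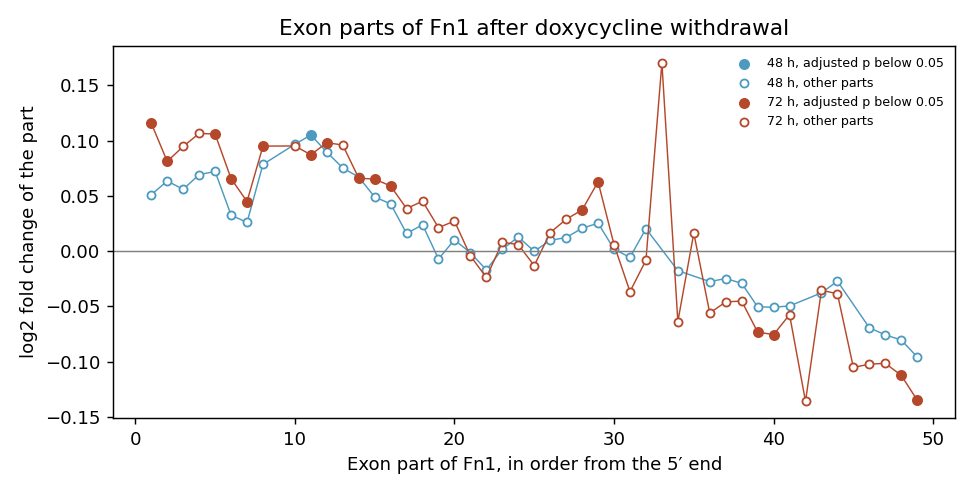
log2 fold change of each exon part of Fn1 from the 5′ to the 3′ end at 48 h and 72 h, as the authors gave them; filled points are parts with adjusted p below 0.05. At 72 h, 13 parts are called higher and 4 lower, most of the higher ones on the 5′ side and the lower ones on the 3′ side.

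Most parts that changed at 48 h had changed in the same direction at 72 h, and, of 5 classes compared, detained introns differed most between the times. Of 408 parts higher at 48 h, 286 (70.1%) were also called higher at 72 h, and of 268 lower parts, 187 (69.8%) were also called lower. Independent lists would share 13.7 and 6.45 parts, and simulated unchanged groups against shared controls shared 113 and 67.3. Of the 676 calls at 48 h with values at both times, 674 (99.7%) had the same sign at 72 h, against 93.4% in the simulation. Part of the excess over independent lists may come from the shared control libraries, which could not be split. The simulation already held shared controls, and under its settings they gave less overlap than was seen. Its parts were drawn independently of each other. A bias of the control libraries that moves many parts together was not simulated, so the simulation sets no limit on what shared controls can give. Over the 189 detained introns tested at both times, the median log2 fold change was 0.03 at 48 h and 0.17 at 72 h, and the difference over 179 genes had a median of 0.13 (95% bootstrap interval 0.10 to 0.15). It was larger at 72 h in 148 of these genes (82.7%). For first exons the same difference had a median of 0.0046 (interval 0.0035 to 0.0060), and for terminal exons -0.019 (interval -0.020 to -0.017).

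Genes of splicing factors changed more often than other genes at both times. For genes of this and the other lists, the part of lowest adjusted p is given. At 72 h, 33 of 53 tested splicing factor genes (62.3%) had a changed part, 29 with a higher and 18 with a lower part, against 18.9% of other genes (odds ratio 7.09, interval 4.06 to 12.4, Fisher's exact test, adjusted p = 1.5e-10; stratified by tested parts, adjusted p = 3.3e-09). The first exon rose in Acin1 (0.28) and Ptbp1 (0.18), a cassette exon rose in Srsf6 (0.54), and an unclassified part rose in Srsf2 (0.37), in the authors' deposited table. At 48 h, 11 of 47 splicing factor genes changed, 8 with a higher and 5 with a lower part (Fisher's exact test, adjusted p = 0.0033; stratified, adjusted p = 0.048). Adjusted over the list alone, 38 genes changed at 72 h and 20 at 48 h. The stratified tests matched genes on the number of tested parts and not on counts. A higher chance of calls in highly expressed genes was therefore not controlled, for this list or the others.

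Another 3 lists changed more often than other genes at 72 h. For each, the adjusted p no longer passed 0.05 once genes were compared within groups of similar numbers of tested parts. The stratified odds ratios at 72 h stayed above 1. They were 2.90 (interval 1.32 to 6.35) for chromatin regulators, 2.47 (1.22 to 4.98) for DNA replication and 2.69 (1.14 to 6.35) for cleavage and polyadenylation. Of long chromatin and transcriptional regulator genes, 15 of 30 changed (Fisher's exact test, adjusted p = 0.0018; stratified, adjusted p = 0.091), 13 with a higher and 10 with a lower part. The terminal exons of Chd2 (-0.22) and Setd5 (-0.12) fell, and parts near the 5′ end rose in Chd4 (0.12) and Arid1a (0.11), per the authors' deposited table. Of DNA replication genes, 16 of 37 changed (Fisher's exact test, adjusted p = 0.0072; stratified, adjusted p = 0.096), 13 with a higher and 7 with a lower part. Besides Rfc5, a detained intron rose in Pola2 (0.34), the first exon in Mcm3 (0.10) and an internal part in Mcm7 (0.05), in the authors' deposited table. Of cleavage and polyadenylation genes, 11 of 23 changed at 72 h, 9 with a higher and 3 with a lower part (Fisher's exact test, adjusted p = 0.0093; stratified, adjusted p = 0.15) and 6 of 21 at 48 h (Fisher's exact test, adjusted p = 0.013; stratified, adjusted p = 0.093). Parts rose in Pabpc4 (0.44), in Cpsf7 (0.12) and in Sympk (0.29), an intronic polyadenylation part, and an internal part fell in Pabpc1 (-0.06), in the authors' deposited table. Adjusted over the list alone, 15, 19 and 11 genes of these lists changed at 72 h, and 6 cleavage and polyadenylation genes at 48 h.

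**Figure D4:**
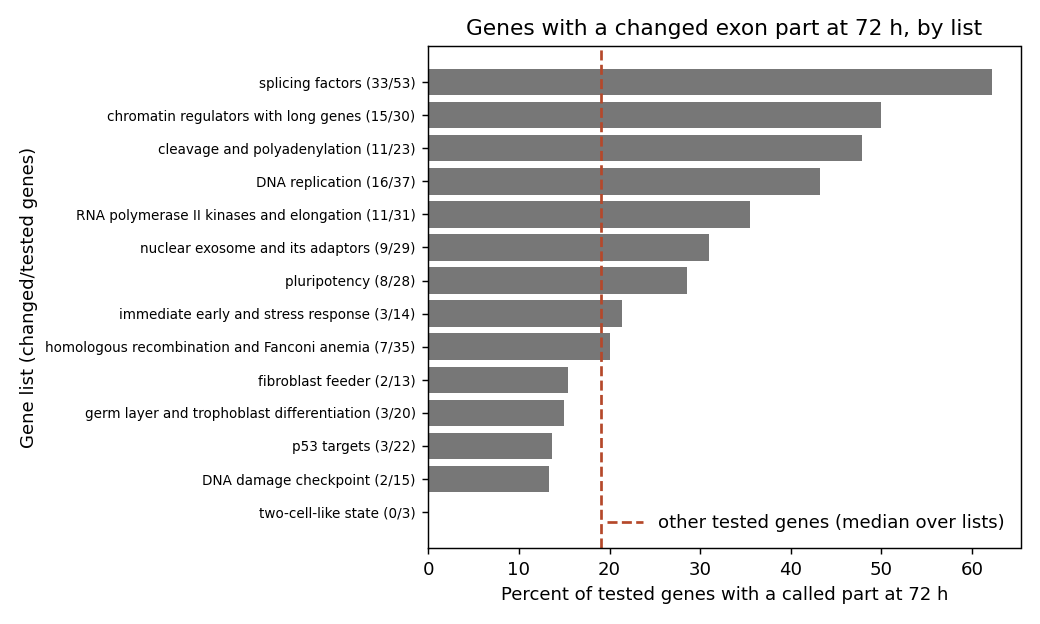
Percent of tested genes with a called exon part at 72 h in each of 14 gene lists, with changed over tested genes beside each name; the dashed line is the share among other tested genes. Splicing factor genes reach 62.3%, against 18.9% of other genes.

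The remaining lists were not shown to differ from other genes after adjustment. Of nuclear exosome and adaptor genes, 9 of 29 changed at 72 h, 7 with a higher and 6 with a lower part (Fisher's exact test, adjusted p = 0.38). Among the exosome and adaptor genes at 72 h, detained introns rose in Srrt (0.58) and Zc3h18 (0.40), which encode proteins that link the exosome to the cap-binding complex, an intronic polyadenylation part rose in the exosome nuclease gene Exosc10 (0.45), and the first exon rose in the cap-binding gene Ncbp2 (0.16), in the authors' deposited table. Of RNA polymerase II kinase and elongation genes, 11 of 31 changed at 72 h, 8 with a higher and 5 with a lower part (odds ratio 2.34, interval 1.12 to 4.89, Fisher's exact test, adjusted p = 0.11). Cdk13, the gene that was withdrawn, was itself among the changed genes. The first exon of Supt5h (0.22) and a 5′ part of Supt6h (0.09) rose and the terminal exon of Polr2b fell (-0.13), in the authors' deposited table. Of homologous recombination and Fanconi anemia genes 7 of 35 changed, 4 with a higher and 3 with a lower part, against 19.1% of other genes (odds ratio 1.06, interval 0.462 to 2.43, Fisher's exact test, adjusted p = 1.0). Within that list the terminal exons of Brca1 (-0.10) and Rad51l3 (-0.37) fell and detained introns of Fanci (0.56) and Dna2 (0.73) rose, in the authors' deposited table. Among DNA damage checkpoint genes, 2 of 15 changed, 1 with a higher part and both with a lower one, with a fall of the terminal exon in Mdc1 (-0.19) in the authors' deposited table. Under the name Rnf8 the internal parts E026 (0.21), E033 (0.15) and E035 (0.17) and the detained intron E010 (0.38) rose, in the authors' deposited table. Parts E006 (-0.28), E011 (-0.37), E016 (-0.38) and E017 (-0.30) of that name fell, and they lay 5′ of the internal parts that rose, in the authors' deposited table. The parts that fell ended at 29772967 on chromosome 17, and the internal parts that rose began only at 29811084. Whether both groups belong to 1 gene was not checked, so their opposite directions are not read as a change within Rnf8. The Rnf8 parts besides E026 were chosen after their values were seen. Adjusted over the list alone, the counts were 11, 11, 6 and 2 in the order given.

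Lists for cell state and stress were not shown to differ from other genes after adjustment either. Of pluripotency genes, 8 of 28 changed at 72 h, 4 with a higher and 5 with a lower part (Fisher's exact test, adjusted p = 0.49). The terminal exons of Sall4 (-0.20) and Trim71 (-0.08) fell, and the first exon of Dppa4 (0.15) and a detained intron of Stat3 (0.40) rose, in the authors' deposited table. Of germ layer and trophoblast genes 3 of 20 changed, with a fall in Dnmt3b (-0.08) and rises in Lefty1 (0.05) and Tfap2c (0.05) in the authors' deposited table. The p53 target list also holds Trp53, the gene of p53 itself. Of its genes 3 of 22 changed, 3 with a higher and 1 with a lower part, with rises in Trp53 (0.03), Aen (0.13) and Sesn2 (0.08) in the authors' deposited table. Of immediate early and stress genes 3 of 14 changed, also 3 with a higher and 1 with a lower part, with a fall of the terminal exon of Dnajb1 (-0.12) and rises in Mycn (0.07) and Hspa8 (0.01), in the authors' deposited table. Markers of fibroblast feeder cells changed in 2 of 13 genes, both with higher and lower parts, Fn1 (0.10 for E057) and Sparc (0.09 in the authors' deposited table), and none of 3 tested genes of the two-cell-like state changed. For the germ layer, p53, immediate early, feeder, two-cell-like and checkpoint lists the adjusted p of Fisher's exact test was 1.0. Adjusted over the list alone, the counts were 11, 3, 3, 3, 2 and 0 in the order given. At 48 h no list besides splicing factors and cleavage and polyadenylation passed, and the next lowest adjusted p was 0.098 (Fisher's exact test), for chromatin regulators, of which 5 of 24 changed. The counts at 48 h were 6 of 35 for DNA replication, 5 of 27 for the exosome, 3 of 28 for polymerase kinases and elongation, 2 of 19 for p53 targets, 1 of 26 for pluripotency, 1 of 14 for checkpoint, 1 of 10 for germ layer and 1 of 3 for feeder genes. None of 23 homologous recombination, 12 immediate early and 1 two-cell-like genes tested at 48 h changed. Adjusted over the list alone, the 48 h counts were 7 for chromatin regulators, 10, 6, 3, 4, 3, 1, 3 and 1 in the order given, and 0, 2 and 0 for the last lists. Relative use of parts does not show whether any of these genes was expressed more or less.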

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

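The results here were picked out after the data were seen. A single part was called at both times in opposite directions: a first exon of Rnasek (E014, chromosome 11, 70052440 to 70053332, minus strand) stood at 0.078 at 48 h with adjusted p of 0.0018 and at -0.064 at 72 h with adjusted p of 9.0e-04, in the authors' deposited table. The difference between the times was not tested, and no explanation was weighed.

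Parts in 3 classes that the header of the authors' deposited table does not define were counted with the other parts in the class comparisons and are not described there as classes of their own. Of 89 tested at 72 h, 3 were called, and each was higher, among them Saa3 E004 (0.44) and Copz1 E002 (0.04) in the authors' deposited table. None was called at 48 h.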

How the results depend on the processing

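No paired analysis was possible because the deposited table has no values per library, so the replicate numbers that the conditions share could not enter a fit. For the same reason the fits with other scalings, filters on counts, without the clone, within 1 clone or with a library left out were not run, nor was a minimum mean count of 10, and the stratified list tests used the number of tested parts alone. What depth limits could not be assessed, and why parts lack an adjusted p is not recorded. Chosen after seeing the data were the restriction to parts tested at both times, the position tests by class of part and the lists by detained introns.

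Counts of calls moved with the threshold by construction. At adjusted p below 0.01, 303 parts were called at 48 h, 1877 at 72 h and 183 at both times, and below 0.1, 1194 at 48 h and 809 at both times. At an absolute log2 fold change of at least 1, 0 were called at 48 h, 32 at 72 h and 0 at both times. With only parts tested at both times, 2442 were called at 72 h. The position result kept its direction and passed in 7 alternatives per time, with odds ratios from 29.9 to 172 at 48 h and from 12.6 to 28.15 at 72 h. It did not pass at an absolute log2 fold change of at least 1 at 72 h (2.00, from 31 calls). Under that same minimum the classes rested on 1 to 4 parts: 75% of first exons were higher, a smaller share than of other parts, and 100% of terminal exons, of detained introns and of intronic polyadenylation parts. At adjusted p below 0.01 at 48 h, 0% of detained introns (1 part) and 33.3% of intronic polyadenylation parts (3 parts) were higher. Among parts tested at both times, 24.2% of called intronic polyadenylation parts were higher at 72 h, against 57.0% of all called ones, and the cause was not tested.

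At 48 h, 0 lists passed at adjusted p below 0.01, at the minimum fold change, with at least 2 changed parts per gene and with detained introns only, 1 list, splicing factors, passed when stratified, and at 0.1 DNA replication passed too. At 72 h, 1 list, splicing factors, passed at 0.01 and when stratified, and 0 passed at the minimum fold change and with detained introns only. Cleavage and polyadenylation also dropped out at 0.1, where 4 lists passed with polymerase kinases and elongation gained, and with at least 2 changed parts, where 3 lists passed. Of 84 named parts and times, 68 stayed past adjusted p of 0.01 and 14 had an absolute log2 fold change of at least 1.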

Other observations

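Tests chosen only after the result was seen were those of RNA integrity numbers, of interior exons alone, of carried-over unspliced RNA, of detained introns in splicing factor genes and of exons of decay transcripts, among 13 in all, and the genes of the next 2 paragraphs were chosen after their values were seen. Detained introns with the lowest adjusted p at 72 h lay in genes of varied function. They were higher in Plin3 (0.83), which coats lipid droplets, in the glycolytic genes Gpi1 (0.76) and Ldhb (0.60), in Ckap2 (0.59), in Hspg2 (1.05), the heparan sulfate proteoglycan perlecan, in Sulf2 (0.56), a heparan sulfatase, and in the RNA export helicase gene Ddx39b (0.47), in the authors' deposited table. Gse1 had both a higher detained intron (0.53) and a lower terminal exon (-0.51) at 72 h in the authors' deposited table.

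Of the 33 splicing factor genes with a changed part at 72 h, 20 had at least 2. Detained introns rose in Srsf1 (0.91), in Prpf4b (0.51), in Rbm10 (0.52) and at 3 places in Rbm5 (0.52, 0.81 and 0.66), and fell in Luc7l3 (-0.23), in the authors' deposited table. Intronic polyadenylation parts rose in the splice-site recognition gene U2af1 (0.86, a part of only 3 bp), in Smad1 (0.82) and in Mat2a (0.68), the S-adenosylmethionine synthetase gene, and fell in Nrp2 (-0.49) and in the histone methyltransferase gene Suv39h1 (-0.56), in the authors' deposited table.

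The shift of use toward the 5′ end was not carried by the first and terminal exons alone: over interior unclassified parts at 72 h the most 5′ of 3 groups was higher than the most 3′ one in 68.6% of 5074 genes (95% exact binomial interval 67.3 to 69.9). A difference in 3′ coverage bias between libraries, which would grow with transcript length, stays open. The prediction fixed for it beforehand was a gradient that rises with exonic length and not with genomic span. That prediction was met, though the correlation was weak. The gradient rose with exonic length at a given genomic span (partial Spearman 0.0728 across 6682 genes, permutation p = 1.0e-05, the smallest that the permutations can give, adjusted over 4 correlations 2.0e-05). RIN did not lie higher without doxycycline (difference -0.05, exact permutation p = 0.72, 8 against 4 libraries), which leaves a small difference in integrity open. A biological candidate was loss of transcripts over genomic distance after Cdk13 withdrawal. Its prediction, a rise with genomic span at a given exonic length, was not met (partial Spearman 0.0219, interval -0.0018 to 0.046, permutation p = 0.072, adjusted 0.095). A weaker dependence on distance is not excluded. At 48 h, across 2763 genes, the partial Spearman with exonic length was 0.094 (interval 0.057 to 0.131, permutation p = 1.0e-05). With genomic span it was 0.0029 at 48 h (interval -0.035 to 0.041, permutation p = 0.88). Genes are not independent replicates, and without values per library a technical and a biological source of the gradient cannot be told apart.

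The rise of detained introns at 72 h was compared with 3 technical explanations. Position alone does not account for it, since detained introns exceeded unclassified parts in each of 5 position groups along the gene, by at least 0.15. An effect of low counts stays open. Among parts without an adjusted p at 48 h, detained introns stood 0.16 above unclassified parts (median over genes, interval 0.15 to 0.18). Why parts lack an adjusted p is not recorded, so the kinds of part were not matched on counts as that test had assumed. The 189 detained introns tested at both times had a median of 0.03 at 48 h and 0.17 at 72 h, against the same controls. Unclassified parts tested at both times stood at 0.0027 at 72 h and intronic polyadenylation parts at -0.03. Counts were not matched for these 189 introns either, and depth per library is unknown, so these values do not decide on low counts. Unspliced RNA or DNA carried over for every intron also stays open, since detained introns stood 0.11 above intronic polyadenylation parts in 380 genes with both (interval 0.08 to 0.15) without a match on counts, and ordinary introns are not among the classes. A candidate explanation beside these is that Cdk13 withdrawal favours transcripts with detained introns, as a hypothesis found and tested on the same data, and slower splicing and slower decay were not separated. Removal of doxycycline itself was not separated from Cdk13 withdrawal either.

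Exons used only in transcripts annotated for nonsense-mediated decay were called higher more often than exons of coding transcripts at 72 h: matched by width within the gene to GENCODE M21, 10 of 217 such internal parts (4.61%) were higher and 3 lower, against 895 of 60015 (1.49%) higher and 356 lower for coding exons (odds ratio for higher 3.19, interval 1.69 to 6.04, Fisher's exact test, p = 0.0018). The excess was not shown to have a direction: 76.9% of called parts were higher, against 71.5% of called coding exons (odds ratio 1.33, interval 0.363 to 4.85, Fisher's exact test, p = 1.0), and the odds ratio of being called lower was 2.35 (interval 0.748 to 7.38, Fisher's exact test, p = 0.14). Ap3d1 (0.77), Max (0.35), Srsf3 (0.50) and Nop56 (0.30) were among the higher ones in the authors' deposited table. Splicing factor genes alone do not account for this (odds ratio 2.98 without them, interval 1.52 to 5.83, Fisher's exact test). An effect of low counts may remain, as counts could not be matched (among parts without an adjusted p at 48 h, such exons minus coding ones had a median difference over genes of 0.0016, interval -0.04 to 0.05), and a match by width can be wrong.

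The following hypotheses were tested on intronic polyadenylation and on splicing factors. Intronic polyadenylation parts were not shown to stand above their nearest upstream unclassified part at 72 h. The median difference over 1312 genes was 0.0012 (interval -0.01 to 0.02), and the part was above its neighbour in 50.2% of genes. A sign permutation test of the mean difference, 0.013, gave p = 0.10. Use fell from the 5′ to the 3′ end of genes, which lowers a part against an upstream one, so a rise stays open. A lower terminal exon was found in 9 of 45 genes with a higher intronic polyadenylation part and in 123 of 1050 others (odds ratio 1.88, interval 0.886 to 4.01, Fisher's exact test, p = 0.10), which leaves the association open. Detained introns of splicing factor genes were called higher at 17 of 60 (28.3%), against 368 of 2549 (14.4%) elsewhere (odds ratio 2.34, interval 1.32 to 4.15, Fisher's exact test, p = 0.0052). Counted by gene rather than by intron, the splicing factor list did not pass adjustment over the lists.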
